A study of Mus musculus with 68 samples.

How the data were processed

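RNA from bone-marrow granulocytes and spleens of mice negative or positive for S100A9 (also called MRP14) was measured on Affymetrix Mu11K arrays. Per the labels, erythrocytes were removed from the granulocytes, total RNA was extracted with RNeasy columns and biotin-labelled by in-vitro transcription, and each RNA sample was run on sub-array A (6584 probe sets) and on sub-array B (6595 probe sets). The 34 RNA samples, 17 of each genotype, gave 68 arrays. Per the labels, the authors computed the deposited values with MAS5; the MAS5 version was not given in the sources used here. The deposited values are intensity on a linear scale, 1 signal per probe set and array, scaled by the authors to a target of 1000 per the labels, and the values themselves show that each array has a mean of 999 to 1000 after trimming 2% of probe sets at each end. Detection calls were not analysed here. The number of arrays limits the precision of every value.

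Samples were grouped by genotype and condition from the labels, giving 14 groups. The labels do not say whether replicates were separate animals or whether RNA was pooled over animals, so p-values measure the spread between these samples. The original experiment names in the labels carry an experiment number and a date code, and the 34 samples fall into 15 experiments and 9 date codes. Negative and positive samples of the same replicate number share an experiment number. Pairing was checked by correlating, across probe sets, the residuals of samples after removal of group means. Correlations of same-number samples ran from 0.0851 to 0.366 at control 4 h, 0.199 to 0.590 under A23187 and 0.140 to 0.190 under LPS, with 0.0983 at control 0 h, and the experiment number was therefore tried as a block. No pair of samples was identical, and the highest correlation between 2 samples was 0.954, for the spleens.

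The 122 hybridisation-control, housekeeping-control and yeast probe sets were removed; removal of the yeast probe sets was decided after the design had been fixed. Of the 13057 remaining probe sets, 7542 matched 1 gene in the annotation, 224 several and 5291 none, and 5861 genes were represented. Probe sets with a signal of at least 400 in at least 2 RNA samples were kept, leaving 12206. Signals were analysed as log2(signal + 100) with limma 3.58.1 in R 4.3.3, with names matched in Python 3.11.15. A group-means model was fitted by lmFit and moderated by eBayes with an intensity trend, with 20 residual degrees of freedom, so that groups of 1 or 2 samples are assumed to vary like the others. Adjusted p-values are Benjamini-Hochberg values over all 12206 probe sets within a comparison, two-sided, with a threshold of 0.05. The 14 comparisons were negative against positive at control 4 h, at control 0 h, under A23187, under LPS and averaged over granulocyte conditions (weighted by replicates); LPS, A23187, PMA and LTB-4 against control 4 h, control 4 h against control 0 h, LPS against A23187 and spleen against control 0 h, each averaged over genotypes; and the genotype by LPS and genotype by A23187 interactions. Log2 differences are given with the standard error of the fit, and signals as mean and SD.

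The groups, model, filter, comparisons, gene lists, named-gene rule and first set of other settings were fixed before the data were examined. The lists comprised 20 gene lists (azurophil granule proteins; specific and gelatinase granule proteins; S100 family; NADPH oxidase; neutrophil adhesion and chemotaxis; actin and tubulin cytoskeleton; cytokines and chemokines; NF-kB pathway and its feedback; endotoxin response effectors; interferon response; immediate early and calcium-regulated transcription factors; endoplasmic reticulum stress; heat shock response; calmodulin and calcium signalling; glycolysis and hypoxia; apoptosis regulators; cell cycle and DNA replication; oxidative stress and metallothionein; ribosomal proteins; arachidonate and lipid mediator enzymes). They also comprised 9 marker lists for other cells the preparations could hold, namely erythroid, B lymphoid, T and natural killer, monocyte with macrophage and dendritic, MHC class II, eosinophil with basophil and mast, megakaryocyte and platelet, stroma and endothelium, and sex-linked transcripts. Each gene was represented by its probe set with the highest mean signal. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Counts of members are given over all probe sets and adjusted over the list alone. Named genes were S100a9 and S100a8 in every comparison, up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold with the same sign in each genotype, up to 4 members per list with the smallest adjusted p, and all genes where 24 or fewer passed.

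Other settings tried comprised quantile normalization, other pseudocounts and filters, no trend, each sub-array alone, array weights, only the compared groups in the fit, experiment number or date code as a block, early or late date codes as a covariate, early or late date codes alone, averaging A23187 replicates 1 and 2 (which share an experiment number), and leaving out each RNA sample in turn. Leaving out 9 dim RNA samples (2nd percentile of signal above 45 on both sub-arrays), the array floor (log2 of that percentile) as a covariate, and the replicate number as a block were added after the data had been seen. The pipeline was tested on simulated data with independent noise. A change of 2 on the log2 scale, up or down, was called for 63 of 100 changed probe sets in the genotype comparison at control 4 h. The number was 90 for LPS, 95 for A23187, 37 for PMA, 26 for LTB-4, and 6 and 8 in the interactions. False calls were at most 9.8% of calls, for LPS against A23187. Of 20 simulated lists, the preset correlation called the 1 raised list and 1 unchanged list, and the estimated correlation called the raised list alone. Date codes, pairs and dim arrays were not simulated, so recovery under that structure is not known.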

Results

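Gene expression was measured in bone-marrow granulocytes of S100A9-negative and S100A9-positive mice, and in spleen tissue for comparison. S100A9 is a calcium-binding protein that forms a heterodimer with S100A8 and is among the most abundant proteins of neutrophils. Granulocytes were taken unstimulated at 0 h (2 samples per genotype) or after 4 h (5 per genotype), or were stimulated for 4 h. The stimuli were leukotriene B4 (LTB-4, a chemoattractant lipid; 1 per genotype), A23187 (a calcium ionophore; 4 per genotype), bacterial lipopolysaccharide (LPS; 3 per genotype) and the phorbol ester PMA (an activator of protein kinase C; 1 per genotype). Spleen gave 1 sample per genotype; the title of the positive sample says spleen while its source field names granulocytes, and it was grouped as spleen. Median signals on sub-array A ran from 393.9 to 672.4 over the 34 RNA samples. In 9 of them the lowest signals were raised on both sub-arrays: the 2nd percentile on sub-array A was 49.0 to 71.5, against 14.8 to 38.4 in the others. These 9 dim samples comprised all 4 samples at 0 h, 4 of the 8 A23187 samples (replicates 2 and 3 of each genotype) and negative control 4 h replicate 3. Their median ratio of 3' to 5' actin signal, a sign of RNA integrity, was 2.71 against 1.21 in the others, among which it was highest, at 4.58, in the positive PMA sample (1.08 in the negative). Negative and positive samples of each replicate number shared a date code in the labels, except those of control 4 h replicate 5, whereas treatments mostly did not.

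**Figure D1:**
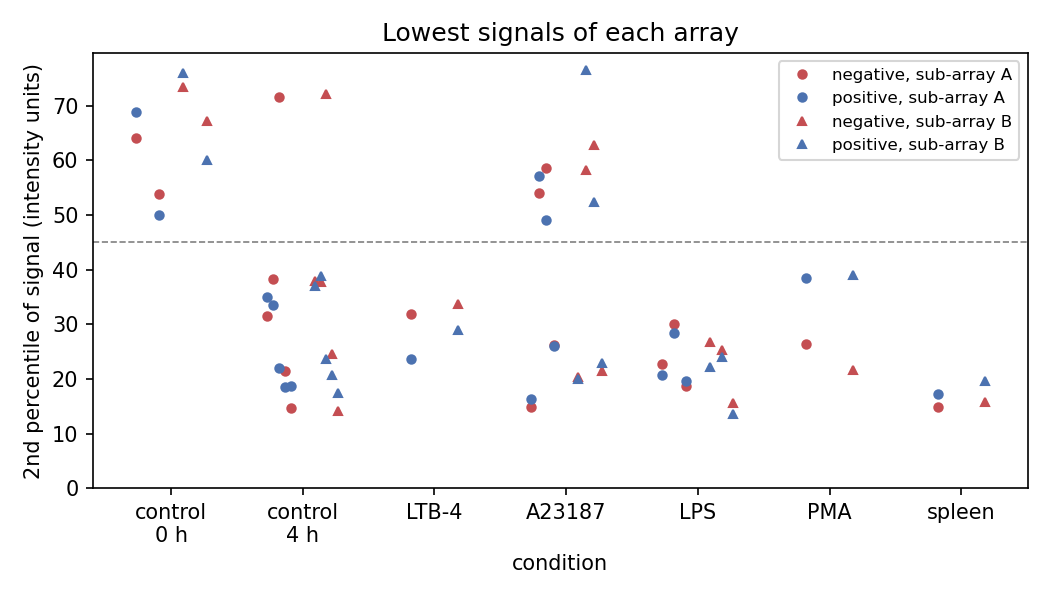
Lowest signals of each array, given as the 2nd percentile of signal in intensity units, by condition; each point is 1 array, colour gives the genotype and shape the sub-array. The dashed line at 45 separates the arrays of the 9 dim RNA samples, which include all 4 samples at 0 h.

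Whether negative granulocytes lacked the S100a9 transcript was asked first. S100a9 RNA was far lower in negative granulocytes in every condition, while S100a8, the transcript of its partner, did not differ past the threshold. At control 4 h the S100a9 signal (sub-array A) was 360 ± 152 (SD, n = 5) in negative and 141950 ± 45320 (SD, n = 5) in positive samples, a log2 difference of -8.30 ± 0.48 (SE; limma adjusted p = 2.8e-14), with every negative sample below every positive sample. The log2 difference was -7.22 ± 0.77 at 0 h (adjusted p = 5.94e-07), -7.09 ± 0.54 under A23187 (adjusted p = 8.41e-11) and -4.82 ± 0.63 under LPS (adjusted p = 6.74e-05). Under LPS the adjusted p became 0.225 when only the LPS samples were fitted. Averaged over granulocyte conditions it was -7.09 ± 0.27 (adjusted p = 3.74e-20), with signals of 102.5 to 5831 in the 16 negative and 44999 to 206449 in the 16 positive samples. The S100a8 difference averaged over conditions was -0.08 ± 0.28 (95% interval -0.66 to 0.49, adjusted p = 0.998). In spleen the S100a9 signal was 101.2 in the negative and 3746 in the positive sample.

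**Figure D2:**
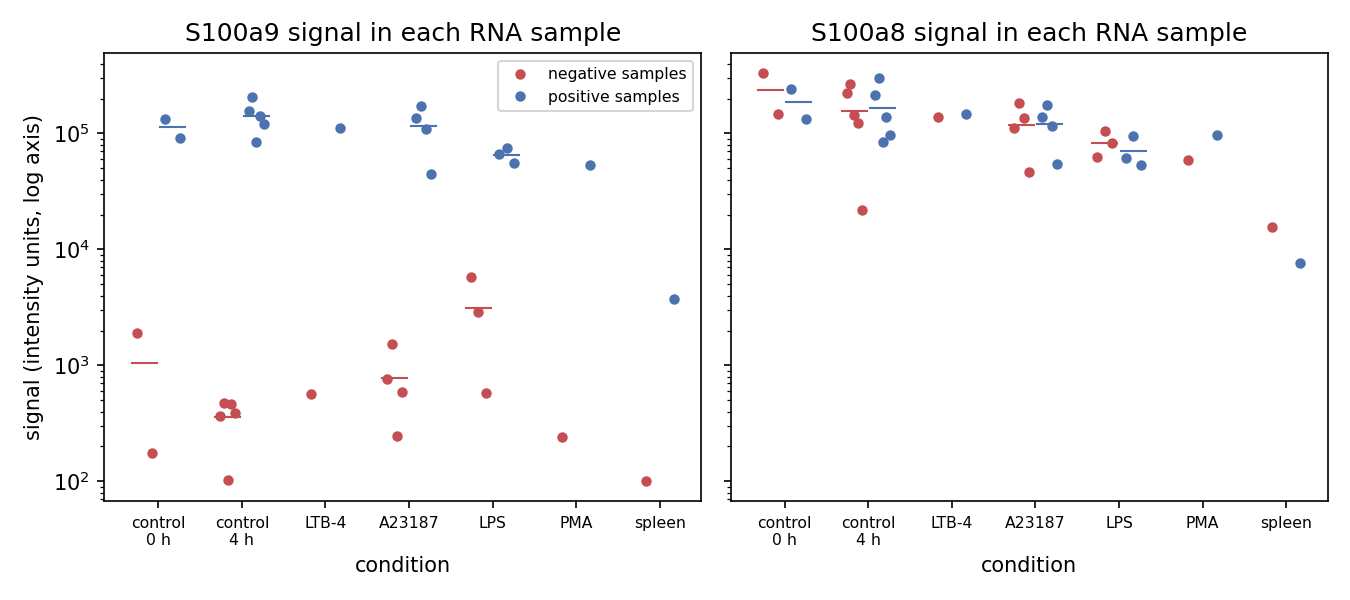
Signal of S100a9 (left) and S100a8 (right) on sub-array A, in intensity units on a log axis, by condition; points are RNA samples coloured by genotype, and lines are group means where a group has 2 or more samples. All 16 negative granulocyte samples lie below all 16 positive samples for S100a9, and the genotypes overlap for S100a8.

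Whether loss of S100A9 changed other transcripts was asked within each condition and over all of them. At control 4 h, under A23187 and under LPS, S100a9 itself was the 1 probe set of 12206 that passed. By limma 324, 403 and 60 probe sets had an unadjusted p under 0.05, where chance gives 610.3. This fit did not pair samples, although samples of the same replicate number correlated. Counts below chance do not show that other transcripts were unchanged. With simulated independent noise, a log2 change of 2 was called for 63, 51 and 42 of 100 changed probe sets in these comparisons. With the replicate number or the experiment number as a block, Ctss, which encodes the lysosomal protease cathepsin S, also fell at control 4 h (-1.51 ± 0.23, adjusted p = 0.00988, and adjusted p = 0.028). Under A23187 the count was 2 without positive A23187 replicate 1. Averaged over conditions, 7 probe sets passed, 1 higher and 6 lower in negative samples, with 426 at an unadjusted p under 0.05. Besides S100a9 they included Ctss, at 2882 ± 887 in negative and 6898 ± 3568 in positive samples (n = 16 each), a log2 difference of -1.11 ± 0.19 (adjusted p = 0.0058). Serinc3, a multipass membrane protein, fell by 1.04 ± 0.18 on the log2 scale (adjusted p = 0.00595), as did its second probe set. Efhd2, a calcium-binding adaptor protein, fell by 1.15 ± 0.22 (adjusted p = 0.0149), although its other probe set had the opposite sign. Without the 9 dim samples, and so with fewer samples, Efhd2 (-1.23, adjusted p = 0.185) and Serinc3 (-0.96, adjusted p = 0.293) no longer passed, and without positive control 0 h replicate 1 Efhd2 did not (adjusted p = 0.0552). None of the 3 genes passed within the early or the late date codes alone, where Ctss differed by -1.29 and -0.94.

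At 0 h, 15 probe sets differed between genotypes, 4 higher and 11 lower in negative samples, with 1146 at an unadjusted p under 0.05. Ercc1, an endonuclease subunit of nucleotide excision repair, fell by 3.05 ± 0.50 on the log2 scale (adjusted p = 0.00295, n = 2 per genotype). Myd88, the adaptor of Toll-like receptors, fell by 2.05 ± 0.41 (adjusted p = 0.0405), as did Fasn, Ddr2 and Actn3, while Smn1 rose by 2.73 ± 0.53 (adjusted p = 0.034) and Ift81 also rose. Plekha1 fell, but not with the experiment number as a block (adjusted p = 0.0626). Of the 9 named genes, the 8 other than S100a9 lost their call with array weights, with only the compared groups in the fit (for Ercc1 adjusted p = 0.99981), within early or late date codes, and without negative or without positive replicate 1. The count was 53 with the replicate number as a block, 43 after quantile normalization and 37 with the array floor as a covariate. RNA quality differed among the 0 h samples. The 3' to 5' actin ratio on sub-array A was 10.03 in positive replicate 1, the highest of all samples, and 2.03 in positive replicate 2. It was 3.86 and 2.81 in negative replicates 1 and 2. All 4 samples were dim arrays, and the count was 4 without negative replicate 1, 26 without negative replicate 2, 2 without positive replicate 1 and 105 without positive replicate 2. A test of whether the genotype difference itself differed between 0 h and 4 h, added after the data had been seen, found 0 probe sets by limma (898 at an unadjusted p under 0.05), and 0 of the 15.

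No gene list differed between genotypes with an estimated correlation. Specific and gelatinase granule proteins, the secretory proteins of mature neutrophils, were lower in negative samples at control 4 h with the preset correlation (10 of 13 members lower, adjusted p = 0.036), with 0 members past the threshold (adjusted p = 0.880 with an estimated correlation). The S100 family was lower there too (adjusted p = 0.023, or adjusted p = 0.0697 with an estimated correlation), with S100a9 the 1 member of 8 that fell, also when adjusted over the list alone. Heat shock genes were higher in negative samples under A23187 (10 of 11 members, adjusted p = 2.77e-04) and averaged over conditions (adjusted p = 0.0159), with 0 members past the threshold (adjusted p = 0.280 and adjusted p = 0.967 with an estimated correlation). B lymphoid markers were higher under A23187 (adjusted p = 0.0295, or adjusted p = 0.520 with an estimated correlation), and eosinophil, basophil and mast cell markers lower under LPS (adjusted p = 0.0227, or adjusted p = 0.0666 with an estimated correlation), again with 0 members past the threshold.

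Whether genotype altered the response to a stimulus was tested by interactions. By limma, 0 probe sets passed for LPS (108 at an unadjusted p under 0.05) and 0 for A23187 (276 at an unadjusted p under 0.05). For S100a9 the LPS interaction was 3.47 ± 0.79 (95% interval 1.86 to 5.08, adjusted p = 0.99989). It passed with the experiment number as a block (adjusted p = 0.0265), with the replicate number as a block (adjusted p = 0.0278) and without negative LPS replicate 3 (adjusted p = 0.0247, interaction count 1), while its other settings gave adjusted p from 0.108 to 1. The A23187 interaction of S100a9 was 1.20 ± 0.73. In the LPS interaction, specific granule proteins (adjusted p = 0.00156, or adjusted p = 0.444 with an estimated correlation) and the S100 family (adjusted p = 0.0408, or adjusted p = 0.109 with an estimated correlation) were higher. Eosinophil, basophil and mast cell markers were lower there (adjusted p = 0.0408, or adjusted p = 0.109 with an estimated correlation). The S100 family list holds S100a9 itself and was not tested without it. After quantile normalization none of these lists passed by camera (adjusted p = 0.164, 0.166 and 0.136 in this order). Without dim arrays the granule and S100 lists did not pass (camera adjusted p = 0.101 each).

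LPS, a bacterial cell-wall component sensed through Toll-like receptor signalling, raised inflammatory genes of granulocytes of both genotypes within 4 h. Ccl3, a chemokine, rose from 1211 ± 1105 (SD, n = 10) at control 4 h to 26710 ± 6602 (n = 6), a log2 difference of 4.63 ± 0.28 (adjusted p = 5.59e-14), and lay above every control in 6 of 6 samples. Saa3, an acute-phase protein, rose by 4.86 ± 0.48 (adjusted p = 1.7e-08), Cxcl2, a neutrophil chemoattractant, by 3.94 ± 0.41 and Acod1, which makes itaconate, by 3.70 ± 0.52. Sod2, the mitochondrial superoxide dismutase, rose by 3.10 ± 0.25, Il1b by 2.96 ± 0.32 and Nfkbiz, an NF-kB cofactor, by 2.91 ± 0.27, and Upp1, Ccl5, Ifit1, Cxcl10 and Mxd1 by 3.20 to 3.61. Among the falls were the extracellular matrix genes Fn1 (-3.93 ± 0.34, adjusted p = 7.36e-10) and Vcan (-2.66 ± 0.34), the apolipoprotein gene Apoe (-2.51 ± 0.48), and Tgfbi (-1.77 ± 0.29) and Ahnak (-1.59 ± 0.25). In all, 156 of 12206 probe sets passed, 118 up and 38 down, with 910 at an unadjusted p under 0.05.

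**Figure D3:**
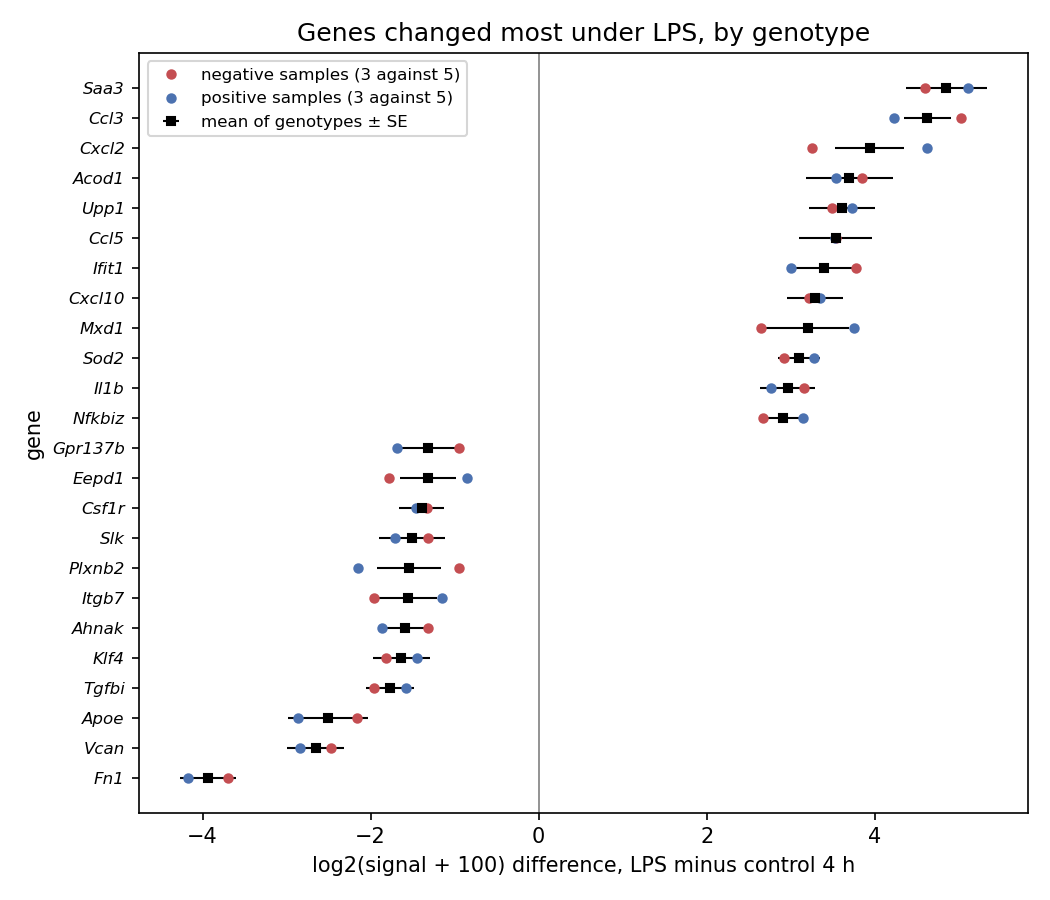
Log2 difference, LPS minus control 4 h, of the 24 named genes with the largest rise or fall; coloured points are the genotypes (3 against 5 samples each), and squares with bars are the mean of the genotypes and its SE. Each of the 24 genes has the same direction in both genotypes.

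Of the fixed lists, 5 rose under LPS with both correlations. Cytokines and chemokines had 10 of 27 measured members up and 0 down (14 up and 1 down adjusted over the list alone; adjusted p = 1.74e-06 with an estimated correlation). Endotoxin response effectors had 8 of 17 up (11 adjusted over the list alone; adjusted p = 5.17e-07 with an estimated correlation), including the LPS co-receptor Cd14 (1.69 ± 0.26). The interferon response had 9 of 26 up (16 adjusted over the list alone; adjusted p = 1.00e-04 with an estimated correlation), including Isg15 (2.76 ± 0.35), Igtp (2.59 ± 0.38) and Irf7 (2.40 ± 0.31). The NF-kB pathway and its feedback had 3 of 15 up (9 adjusted over the list alone; adjusted p = 0.00157 with an estimated correlation), including Tnfaip3 (2.29 ± 0.46) and Bcl3 (1.39 ± 0.28). Birc3 rose, but not with the experiment number as a block (adjusted p = 0.0583). Oxidative stress and metallothionein genes had 5 of 17 up (6 adjusted over the list alone; adjusted p = 0.00748 with an estimated correlation), including Hmox1 (1.55 ± 0.24) and Sqstm1 (1.28 ± 0.27).

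Monocyte, macrophage and dendritic markers moved both ways under LPS. Adgre1 (2.26 ± 0.34) and Vcam1 (1.52 ± 0.29) rose, Csf1r (-1.39 ± 0.27), Ccr2 (-1.17 ± 0.25) and Ctsl (-1.15 ± 0.27) fell, while 11 of 16 did not pass (2 up and 6 down adjusted over the list alone). Within the early and the late date codes alone Csf1r was -2.02 (adjusted p = 0.0996) and -0.72 (adjusted p = 0.554), and Ccr2 -1.15 (adjusted p = 0.997) and -1.19 (adjusted p = 0.0674). The list was lower with the preset correlation (adjusted p = 0.0294, or adjusted p = 0.307 with an estimated correlation). MHC class II genes had 0 of 7 past the threshold and 5 down adjusted over the list alone (adjusted p = 5.67e-04, or adjusted p = 0.153 with an estimated correlation). Of the immediate early and calcium-regulated transcription factors, 3 rose, among them Gadd45b (1.32 ± 0.28), and Klf4 fell (-1.63 ± 0.34; list adjusted p = 0.0495, and adjusted p = 0.223 with an estimated correlation). NADPH oxidase (adjusted p = 0.029, or adjusted p = 0.223 with an estimated correlation) and heat shock genes (adjusted p = 0.0105, or adjusted p = 0.205 with an estimated correlation) were higher with 0 members past the threshold. Ribosomal protein genes were lower with 0 (adjusted p = 0.0185, or adjusted p = 0.435 with an estimated correlation). The arachidonate enzymes were higher by the test (adjusted p = 0.029, or adjusted p = 0.205 with an estimated correlation) and by their mean of 0.35 but not by their median of -0.08, and 1 of 11 rose, the prostaglandin synthase Ptgs2 (2.07 ± 0.41).

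LPS samples and controls shared a single date code, with 2 LPS samples (1 per genotype) against 1 negative control. Within it, where these samples had also taken part in naming the genes, all 46 named genes kept their direction, at a median of 0.985 of the pooled difference. Of the 46, 31 lost their call within the early and 17 within the late date codes alone. Within the single shared date code the median log2 difference was 0.94 for cytokines (0.70 pooled), 0.91 for endotoxin effectors (1.24 pooled), 1.59 for interferon genes (1.15 pooled) and 0.85 for NF-kB genes (0.88 pooled). It was 0.25 for oxidative stress genes (0.06 pooled), -0.06 for monocyte markers (-0.55 pooled) and -0.19 for MHC class II (-0.80 pooled). In that shared date code ribosomal proteins (0.14, pooled -0.34) and NADPH oxidase (-0.05, pooled 0.21) had the opposite sign.

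Treatment with the calcium ionophore A23187 for 4 h left no gene past the threshold against control 4 h. By limma 0 of 12206 probe sets passed (957 at an unadjusted p under 0.05, lowest adjusted p 0.234), in 8 against 10 samples. Ribosomal protein genes were lower with the preset correlation, with 16 of 19 members lower and 7 down adjusted over the list alone (adjusted p = 1.22e-06, or adjusted p = 0.366 with an estimated correlation). B lymphoid markers (adjusted p = 1.82e-04, or adjusted p = 0.278 with an estimated correlation) and MHC class II genes (adjusted p = 0.0263, or adjusted p = 0.506 with an estimated correlation) were also lower. So were endoplasmic reticulum stress genes (adjusted p = 0.0454, or adjusted p = 0.278 with an estimated correlation) and cell cycle genes (adjusted p = 0.0454, or adjusted p = 0.516 with an estimated correlation). Stroma and endothelium markers were higher (adjusted p = 0.0483, or adjusted p = 0.506 with an estimated correlation). Without the dim samples none of these lists passed by camera. The adjusted p ran from 0.0919 for B lymphoid markers to 0.826 for cell cycle genes and stroma markers, with 0.353 for ribosomal proteins. After quantile normalization only the B lymphoid list still passed. The count was 2 without negative A23187 replicate 1 and 3 without positive A23187 replicate 1. A23187 samples and controls shared no date code, and 4 of the 8 A23187 samples were dim arrays.

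PMA was measured in 1 sample per genotype, and 114 of the 149 probe sets that passed fell. The leukocyte actin-binding protein Lsp1 fell from 5922 ± 1822 (SD, n = 10) to 294 ± 243 (n = 2), a log2 difference of -4.03 ± 0.41 (adjusted p = 2.26e-07). The gelatinase Mmp9 (-3.48 ± 0.43), the granulocyte surface marker Ly6g (-3.14 ± 0.41) and the transcription factor Klf2 (-2.54 ± 0.35) fell as well, and all 4 of these genes lay below every control in 2 of 2 samples. The immediate early factor Egr1 (2.41 ± 0.42, adjusted p = 0.00104), the chemokines Ccl3 (2.57 ± 0.41) and Ccl4 (1.91 ± 0.39), the fatty acid-binding protein Fabp5 (2.40 ± 0.47) and lipoprotein lipase Lpl (1.97 ± 0.44) rose. Of the 149 probe sets, 35 were up, with 1304 at an unadjusted p under 0.05. The count was 34 without the negative and 11 without the positive PMA sample, and of the 9 genes named here, Lsp1, Mmp9, Ly6g and Klf2 passed without either of them.

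Of the lists, specific and gelatinase granule proteins had 7 of 13 members down and 0 up under PMA, including Hp (-3.01 ± 0.46), Ltf (-2.84 ± 0.48) and Lcn2 (-2.37 ± 0.46). Adjusted over the list alone 9 were down and 1 up, and the list was lower with the preset correlation (adjusted p = 4.22e-12, or adjusted p = 0.0779 with an estimated correlation). NADPH oxidase had 1 of 6 down, Ncf4 (-1.99 ± 0.42), and 5 adjusted over the list alone (adjusted p = 8.82e-05, or adjusted p = 0.0881 with an estimated correlation). The actin and tubulin list had 4 of 19 down, including Tln1 (-1.83 ± 0.37) and Coro1a (-1.81 ± 0.45), with 5 adjusted over the list alone (adjusted p = 2.85e-06, or adjusted p = 0.147 with an estimated correlation). Myh9 and Actn1, also called in this list, lost their call with the experiment number as a block. Oxidative stress genes had 3 of 17 up (3 adjusted over the list alone; adjusted p = 0.0219, and adjusted p = 0.225 with an estimated correlation): Srxn1, Prdx1 and Hmox1, none of which passed with the experiment number as a block (adjusted p = 0.064, 0.0684 and 0.0761). NF-kB genes (0 of 15 past the threshold, adjusted p = 0.0117; adjusted p = 0.235 with an estimated correlation) and glycolysis genes (0 of 14, adjusted p = 0.014; adjusted p = 0.336 with an estimated correlation) were lower. Calmodulin and calcium genes (2 of 19 down, adjusted p = 0.0135; adjusted p = 0.147 with an estimated correlation) and adhesion genes (Selplg down, adjusted p = 0.014; adjusted p = 0.235 with an estimated correlation) were lower too. Interferon genes were higher as a list (adjusted p = 0.0117, or adjusted p = 0.291 with an estimated correlation), although Ifngr1 fell (-2.20 ± 0.39). The monocyte markers Csf1r (-2.47 ± 0.40) and Adgre1 (-2.21 ± 0.51) fell, while their list did not pass. Of the 39 named genes, 32 lost their call without the negative PMA sample, among them Hp, Lcn2, Ncf4, Coro1a, Selplg, Ifngr1, Csf1r and Adgre1. As many, 32, lost it without the positive PMA sample, among them Ltf, Lcn2, Ncf4, Tln1, Coro1a, Selplg, Ifngr1 and Adgre1.

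LTB-4, measured in 1 sample per genotype, left no gene past the threshold. By limma 0 of 12206 probe sets passed (347 at an unadjusted p under 0.05, lowest adjusted p 0.270). Heat shock genes were higher as a list, in 11 of 11 members, with 0 past the threshold (adjusted p = 1.84e-04, or adjusted p = 0.246 with an estimated correlation). LTB-4 samples and controls shared no date code.

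Unstimulated granulocytes at 4 h were compared with those at 0 h, all of which were dim samples. The LPS co-receptor transcript Cd14 rose from 4941 ± 3105 (SD, n = 4) to 20496 ± 11421 (n = 10), a log2 difference of 2.11 ± 0.30 (adjusted p = 1.68e-04), above every 0 h sample in 10 of 10 samples. Mthfd2, a mitochondrial folate enzyme, rose by 2.65 ± 0.36 and the triglyceride-synthesis enzyme Dgat2 by 2.39 ± 0.35. The integrin Itgav rose by 2.04 ± 0.36, asparagine synthetase Asns by 2.01 ± 0.29, the lectin Clec4d by 2.01 ± 0.34 and the apoptosis inhibitor Birc3 by 1.96 ± 0.28. Hemgn, a haematopoietic nuclear protein, fell by 2.33 ± 0.46 (adjusted p = 0.00313) and Cmbl by 1.93 ± 0.37. With the array floor as a covariate, 43 of the 51 named genes lost their call, Hemgn and Cmbl among them, and Cd14, Mthfd2, Dgat2, Itgav, Asns, Clec4d, Birc3 and Fth1 kept it. In all, 692 probe sets passed, 284 up and 408 down, with 2926 at an unadjusted p under 0.05, against a median shift of all probe sets of -0.20. All 4 samples at 0 h were dim arrays; after quantile normalization, which removes the shift, 459 passed, 289 up and 170 down, and with the array floor as a covariate 34 passed. The count was 264 without negative control 0 h replicate 1, 144 without positive control 0 h replicate 1, 1224 without positive control 0 h replicate 2, 1125 without negative control 4 h replicate 3 and 443 without negative control 4 h replicate 5. Within the date code shared by 4 samples at 4 h and 2 at 0 h, which had also taken part in naming the genes, all 51 named genes kept their direction, at a median of 1.26 times the pooled difference, and within the late date codes 0 probe sets passed.

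As lists, 3 groups were higher at 4 h with both correlations. The NF-kB pathway and its feedback had 5 of 15 members up (8 adjusted over the list alone; adjusted p = 0.0223 with an estimated correlation), including Birc3 and Bcl3 (1.77 ± 0.32). Endotoxin response effectors had 6 of 17 up (9 up and 2 down adjusted over the list alone; adjusted p = 0.0151 with an estimated correlation), including Cd14 and Myd88 (1.11 ± 0.24). Oxidative stress and metallothionein genes had 3 of 17 up (7 up and 1 down adjusted over the list alone; adjusted p = 0.0223 with an estimated correlation), including the ferritin chains Fth1 (1.44 ± 0.28) and Ftl1 (1.24 ± 0.28), neither of which passed after quantile normalization. Erythroid markers had 3 of 10 down, Klf1 (-1.78 ± 0.43), Car2 (-1.58 ± 0.38) and Car1, the last not with the experiment number as a block (adjusted p = 0.0533); the list did not pass (adjusted p = 0.0566). Specific granule proteins (Chil3 up, 1.43 ± 0.29; list adjusted p = 0.00266, and adjusted p = 0.371 with an estimated correlation), NADPH oxidase (Ncf4 up, 1.79 ± 0.32; list adjusted p = 0.0125, and adjusted p = 0.292 with an estimated correlation) and the cytoskeleton (2 of 19 up, list adjusted p = 0.00927; adjusted p = 0.412 with an estimated correlation) were higher. So were adhesion genes (0 of 11 past the threshold, adjusted p = 0.0355; adjusted p = 0.325 with an estimated correlation), glycolysis genes (2 of 14 up, adjusted p = 0.0408; adjusted p = 0.502 with an estimated correlation) and apoptosis regulators (Fas up, adjusted p = 0.0355; adjusted p = 0.239 with an estimated correlation). Ribosomal protein genes were higher (0 of 19 past the threshold, adjusted p = 0.0207; adjusted p = 0.535 with an estimated correlation) but had the opposite direction after quantile normalization (adjusted p = 0.861). With the array floor as a covariate 9 of the genes named here lost their call: Car2 (-1.59) and Fas (1.68 with and without it) at an unchanged difference, and Bcl3 (1.49), Ncf4 (1.55), Klf1 (-1.54), Chil3 (1.18), Car1 (-1.17), Ftl1 (0.91) and Myd88 (0.80) at a smaller one.

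LPS and A23187 were compared directly to ask which genes answered one stimulus more than the other. Saa3 was higher under LPS by 5.73 ± 0.51, Ccl3 by 3.74 ± 0.29 (26710 ± 6602 against 1935 ± 653, SD, n = 6 and 8; adjusted p = 1.23e-10), Isg15 by 3.33 ± 0.36, Il1b by 3.26 ± 0.34, Nfkbiz by 3.16 ± 0.28 and Sod2 by 3.02 ± 0.26, each in 6 of 6 LPS samples. Fn1 (-3.36 ± 0.35), Vcan (-2.44 ± 0.35), Tgfbi (-2.03 ± 0.30) and the S100 family member S100a4 (-1.34 ± 0.27) were lower under LPS. In all, 140 probe sets passed, 117 up and 23 down, with 1458 at an unadjusted p under 0.05 and a median shift of -0.13. Cytokines and chemokines (9 of 27 up, 11 adjusted over the list alone; adjusted p = 9.08e-06 with an estimated correlation) and endotoxin effectors (6 of 17, 9 adjusted over the list alone; adjusted p = 9.08e-06 with an estimated correlation) were higher. Interferon genes (8 of 26, 15 adjusted over the list alone; adjusted p = 1.76e-04 with an estimated correlation) and NF-kB genes (6 of 15, 9 adjusted over the list alone; adjusted p = 0.00155 with an estimated correlation) were higher, as were oxidative stress genes (4 of 17, 7 adjusted over the list alone; adjusted p = 0.00576 with an estimated correlation). Endoplasmic reticulum stress genes were higher (adjusted p = 0.015 with an estimated correlation), with Hspa5 and Herpud1 up, neither with the experiment number as a block (adjusted p = 0.0914 and adjusted p = 0.114). NADPH oxidase genes (adjusted p = 0.016, or adjusted p = 0.177 with an estimated correlation) and heat shock genes (adjusted p = 0.016, or adjusted p = 0.201 with an estimated correlation) were higher. Immediate early (adjusted p = 0.030, or adjusted p = 0.177 with an estimated correlation), cell cycle (adjusted p = 0.00185, or adjusted p = 0.147 with an estimated correlation) and B lymphoid lists (adjusted p = 0.00209, or adjusted p = 0.147 with an estimated correlation) were higher. Stroma markers were lower (adjusted p = 0.00209, or adjusted p = 0.100 with an estimated correlation). Without the dim samples several of these lists did not pass by camera. They were NADPH oxidase (adjusted p = 0.166), heat shock (adjusted p = 0.392), immediate early (adjusted p = 0.172), cell cycle (adjusted p = 0.201) and stroma (adjusted p = 0.200). The B lymphoid list still passed. LPS and A23187 samples shared no date code, and without the dim samples 114 probe sets passed, of which 88 were among the 140.

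Spleen, with its mixed lymphocytes, was compared with granulocytes at 0 h as a reference tissue. MHC class II and T-cell genes were higher in spleen. H2-DMa, which loads peptides on class II molecules, rose from 877 ± 231 (SD, n = 4) to 22264 ± 4486 (n = 2), a log2 difference of 4.54 ± 0.67 (adjusted p = 4.02e-05). Thy1 rose by 4.38 ± 0.64 and Scd1, a fatty acid desaturase, by 3.98 ± 0.46. Granule protein genes were lower, with lactoferrin Ltf at -4.99 ± 0.54 (adjusted p = 2.31e-07), proteinase 3 Prtn3 at -4.76 ± 0.46, Camp at -4.69 ± 0.67, Hp at -4.62 ± 0.52 and Lcn2 at -4.26 ± 0.51. Specific and gelatinase granule proteins had 10 of 13 down (12 adjusted over the list alone; adjusted p = 0.00681 with an estimated correlation) and azurophil granule proteins 3 of 6 down (3 down and 1 up adjusted over the list alone; adjusted p = 0.0496 with an estimated correlation). T and natural killer markers had 5 of 11 up (9 adjusted over the list alone; adjusted p = 0.00414 with an estimated correlation), and MHC class II 4 of 7 up (6 adjusted over the list alone; adjusted p = 0.0218 with an estimated correlation). Eosinophil, basophil and mast cell markers had 3 of 9 down (6 adjusted over the list alone; adjusted p = 0.00681 with an estimated correlation). Heat shock genes had 6 of 11 up (8 adjusted over the list alone; adjusted p = 0.0302 with an estimated correlation). B lymphoid markers had 6 of 15 up and 2 down (adjusted p = 0.00257, or adjusted p = 0.155 with an estimated correlation), with Cd79a up (2.80 ± 0.63) and Rag1, the recombinase of developing lymphocytes, down (-3.23 ± 0.63). With the array floor as a covariate Cd79a was 1.43 (adjusted p = 0.455), and Rag1 (adjusted p = 0.0595) and the B lymphoid list (adjusted p = 0.117) did not pass; neither gene passed when either spleen was left out. Interferon genes (3 of 26 up, adjusted p = 9.69e-04; adjusted p = 0.155 with an estimated correlation) were higher. Cell cycle genes (6 of 31 down and 1 up, adjusted p = 0.00287; adjusted p = 0.183 with an estimated correlation) and erythroid markers (2 of 10 down, adjusted p = 0.0207; adjusted p = 0.155 with an estimated correlation) were lower. With the experiment number as a block the erythroid Car1 (adjusted p = 0.0667) and Car2 (adjusted p = 0.0621), the interferon genes Psmb8 (adjusted p = 0.0537) and Tap1 (adjusted p = 0.0883) and the eosinophil gene Epx (adjusted p = 0.0502) did not pass.

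In all, 681 probe sets passed for spleen, 325 up and 356 down, with 3027 at an unadjusted p under 0.05 and a median shift of -0.36; after quantile normalization 284 were up and 175 down. The count was 83 without the negative spleen, 92 without the positive spleen, 447 without positive control 0 h replicate 1 and 1024 without positive control 0 h replicate 2, and 146 with the array floor as a covariate. Of the 64 named genes, 41 lost their call without the negative spleen, 39 without the positive spleen and 29 with that covariate. Ribosomal protein genes were higher as a list (1 of 19 up, adjusted p = 0.0142; adjusted p = 0.457 with an estimated correlation) but had the opposite direction with that covariate (adjusted p = 0.843). No date code held both spleen and 0 h samples. Actb also fell (-5.91 ± 0.95), but its signal was low in the A23187 samples of the spleens' date code too, and the spleens differed from those by -0.83. Megakaryocyte and platelet markers (1 measured) and sex-linked transcripts (2 measured) had 0 members past the threshold in each of the 14 comparisons.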

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

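Chosen only after the result had been seen were the tests of array scaling and of the array floor for the 4 h comparison, of cross-hybridisation and of a change under LPS for S100a9, the tests on monocyte markers (with scaling taken gene by gene once the joint count of 2 of 3 kept calls was known) and the models with the replicate number as a block or without dim arrays, and the fold-change part of the scaling criterion for the 4 h comparison and its division by kept and lost calls were added once the counts of kept calls were known.

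The change of granulocytes from 0 h to 4 h comprised 284 probe sets up and 408 down, and all 4 samples at 0 h were dim arrays. After quantile normalization all 284 rises and all 408 falls kept their direction. The median rise went from 1.32 to 1.40 (median SE 0.33) and the median fall from -1.56 to -1.31 (median SE 0.39). These values argue against array scaling as the whole cause for the 2 sets, not for each probe set. Both sets were picked as called in the same samples before this normalization, so some of the persistence is built in. Calls were kept by 209 rises (median 1.40, then 1.62 with median SE 0.35) and 161 falls (-1.74, then -1.50 with median SE 0.38). Being picked by that call, these subsets add no evidence on scaling. The calls of 75 rises and 247 falls ended as their differences shrank, so scaling as part of the cause stays open. The 75 rises had a median of 1.08 (median SE 0.30), then 0.74 (median SE 0.27). The 247 falls had -1.47 (median SE 0.42), then -1.21 (median SE 0.40). The criterion as first written would have counted the falls for scaling, since fewer than 50% kept their call. Dimness itself was tested in A23187 samples, as the difference of bright minus dim arrays of 1 genotype in the called probe sets. Its mean was 0.41 (-0.01 to 0.74 over 4 pairs) for the rises and -0.73 (-0.96 to -0.47) for the falls. Replicates 1 and 2, which share a date code, differed by 0.58 (negative) and 0.74 (positive) for the rises and -0.80 and -0.96 for the falls. Replicates 4 and 3, from different date codes, differed by 0.33 and -0.01 for the rises and -0.68 and -0.47 for the falls. Dimness may thus carry a part of the fold, larger in the pairs of 1 date code, and the test does not exclude it as the whole cause. With the array floor as a covariate 34 of the 692 kept their call and direction, Cd14 among them (2.11 with SE 0.30, then 1.68 with SE 0.31). These 34 were picked by that outcome, so their calls do not argue against dimness. The other calls ended as the median absolute difference of the 692 went from 1.49 (median SE 0.38) to 1.04 (median SE 0.41). A change of the cells over 4 h and a low quality of the 0 h arrays were not told apart here, because no 0 h array was bright. Of the 10 samples at 4 h only 1, negative control 4 h replicate 3, was dim. It was not compared on its own with the dim samples at 0 h.

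S100a9 signal, from a probe set whose position relative to the deleted part of the gene is not known here, remained in negative LPS samples, at 5831, 2904.5 and 575.2 in replicates 1, 2 and 3, against at most 475.2 in negative controls at 4 h, but negative samples without LPS also reached 1904.7 (0 h replicate 1) and 1527.1 (A23187 replicate 2), and the log2 genotype by LPS interaction for S100a9 was 3.47 (adjusted p = 1.00 in limma, 0.0265 and 0.0278 with the experiment or replicate number as a block, 0.0247 without negative LPS replicate 3 and 0.108 to 1.00 in the other 30 settings). Cross-hybridisation of the abundant S100a8 transcript was argued against, since S100a8 in these samples was 0.535 of its control level. RNA or cells of positive mice may be a source: the signal was 8.83%, 3.89% and 1.04% of that of the positive sample of the same number, but such a share would shift Efhd2, Ctss or Serinc3 by at most 0.148 on the log2 scale, within their SE of up to 0.22, so the test could not decide. A change under LPS also stays open (exact two-sided permutation p = 0.0179, the smallest that 56 groupings can give, and 0.0357 after adjustment for 2 tests), because replicates 1 and 2 share a date code that holds no control. In positive samples S100a9 was lower under LPS (55157 to 74708) than in every control (83893 to 206449, exact permutation p = 0.0357).

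Monocyte markers moved both ways under LPS, and their list was lower with the preset correlation (adjusted p = 0.0294) but not with an estimated one (adjusted p = 0.307). A loss of monocytes alone would not raise a marker, yet 2 of the list, Adgre1 and Vcam1, rose. That criterion was set once these rises were known, and it cannot decide whether a loss of monocytes carried the falls. Array scaling as the whole cause was argued against for Csf1r (-1.39, then -1.26 with SE 0.24 after quantile normalization) and Ccr2 (-1.17, then -1.12 with SE 0.25), which kept their call, although neither passed within the early or the late date codes alone, where Csf1r was -2.02 and -0.72. For Ctsl, the third marker that fell, the call ended (limma adjusted p = 0.0546), but its change went only from -1.15 (SE 0.27) to -1.07 (SE 0.28). That remaining change argues against scaling as the whole cause for Ctsl too. The criterion as written also asked for a kept call, and by it Ctsl stays undecided. A change of expression within monocytes, or in granulocytes that share these transcripts, was not tested.

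In 22 genes, each tested in 4 groups of 4 or 5 samples, 8 of 88 groups held a sample set far apart from the rest of its group. For normally distributed values chance gives about 5%. The linear signals used were not checked for that, and all genes share the same samples, so 5% is only a rough guide. Values of the other samples of the group are given in brackets. Cd14 was 51346 (16409 to 23414) and Mthfd2 was 13264 (4079 to 5635) in negative control 4 h replicate 4. Dgat2 was 3374.3 (4871 to 5176) in negative control 4 h replicate 3, and Gm10486 was 1423.5 (354 to 526) in negative control 4 h replicate 1. Mthfd2 was 7653.7 (3389 to 4107) in negative A23187 replicate 1, and Mmp9 was 15920 (5730 to 6399) in positive A23187 replicate 1. Hexdc was 4772.3 (453 to 573) and 3072.9 (455 to 601) in negative and positive A23187 replicate 4, which share a date code.

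Other splits of the samples were counted for each comparison with at least 3 samples per group. For the genotype at control 4 h, 3 of 100 splits, the real one included, gave as many calls as the real 1. That 1 call was S100a9, the gene that sets the genotypes apart, so the count says nothing about other genes. The highest other split gave 7. It put replicates 1 and 2 of both genotypes, which share a date code, with positive replicate 5, which points to a structure of the samples. With the experiment number as a block 2 probe sets passed. Of 16 splits that part every pair, the real one gave 1 and the others 0. For the genotype averaged over conditions, 1 of 100 splits, the real one, reached the real 7 (highest other 1). For LPS 1 of 56, again the real one, reached the real 156 (highest other 38). Both shares are under 0.05 without adjustment over the comparisons. The real LPS split also sets replicates 1 and 2, whose date code holds no control, on one side. For 4 h against 0 h 1 of 21 reached the real 692 (highest other 273), the smallest share that 21 splits can give. That split puts all 4 samples at 0 h, all dim, on one side, so its count cannot tell time from dimness. Such shares speak to a random division of the samples only, not to date codes or dimness. Under A23187, 7 of 35 splits gave as many as the real 1. That 1 call was again S100a9. A count of any probe sets does not test S100a9 itself and says nothing about other genes. The highest, 899, divided the dim replicates 2 and 3 from the bright replicates 1 and 4, which points to a structure of the samples. The date code shared by replicates 1 and 2 gave 6 as a split. With the date code as a random block, or without dim arrays, 1 probe set passed, and of 8 splits that part every pair the real one gave 1 and the others 0. For LPS against A23187, 4 of 35 splits reached the real 140, and the 3 larger, up to 553, had all 4 dim arrays on one side; chance cannot be excluded by the count, and without dim arrays 114 probe sets passed, 88 of them among the 140. For A23187 against control 4 h (957 at an unadjusted p under 0.05 by limma) and the LPS and A23187 interactions (108 and 276) the real count was 0, which each of the 100 splits reaches whatever the data, so these counts say nothing about chance. The highest others were 545, 1 and 3, and the split with 545 put all 5 dim samples on one side, with 3 bright ones, which points to a structure of the samples. For the genotype under LPS the 10 splits are too few for a share under 0.05; the real count was 1 and the highest other 0.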

How the results depend on the processing

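Leaving out dim arrays, the array floor as a covariate and the replicate number as a block were chosen only after the results had been seen. Over all settings, 6598 values of named genes kept their side of the threshold, 1126 lost the threshold and 3 gained it. The gains were S100a9 in the LPS interaction, with either block or without negative LPS replicate 3. Among genes called in the main setting 0 reversed. A change of sign in a gene called in neither setting was not counted as a reversal. Of list results 222 kept their direction and side of the threshold, 114 lost the threshold and 2 reversed. Of counts 348 stayed within 1.5 times and 65 did not. With an estimated correlation 20 of 70 list calls held. Causes were not tested unless given. The signal over background limits what could be seen on the dim arrays.

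The ribosomal list reversed for 4 h against 0 h after quantile normalization (adjusted p = 0.861) and for spleen with the array floor as a covariate (adjusted p = 0.843).

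For genotype at control 0 h (15) the count was 43 after quantile normalization, 31 with pseudocount 400, 5 without trend, 9 with each sub-array alone, 1 with array weights, 1 with only the compared groups, 1 within early and 1 within late date codes (1 sample per genotype), 37 with the floor covariate and 53 with the replicate-number block. For genotype at control 4 h (1) either block gave 2. Under A23187 (1) each sub-array alone gave 2. Under LPS (1) array weights gave 2 and only the compared groups 0 (limma, 413 at an unadjusted p under 0.05). Averaged (7), the count was 1 within early and 1 within late date codes, 3 without dim arrays and 12 with the replicate-number block. For the LPS interaction (0) either block gave 1.

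For LPS (156) the count was 368 with array weights, 236 with only the compared groups, 34 within early and 97 within late date codes, where samples are fewer. For A23187 (0) it was 1 with replicates 1 and 2 averaged. For PMA (149) it was 89 without trend, 16 within early date codes and 373 without dim arrays. For LTB-4 (0) it was 1 after quantile normalization, 1 with array weights, 1 without dim arrays and 1 with the floor covariate. For LPS against A23187 (140) it was 221 with array weights and 18 within early date codes.

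For 4 h against 0 h (692) the count was 459 after quantile normalization, 428 with the filter at 1000, 152 with array weights, 296 with the experiment block, 1040 within early and 0 within late date codes (limma, 1041 at an unadjusted p under 0.05), and 34 with the floor covariate. For spleen (681) it was 361 with array weights, 369 with the experiment block, 428 with the date-code block and 146 with the floor covariate.

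Leaving out 1 sample at a time gave 1 to 1 for genotype at control 4 h and under LPS, 6 to 8 averaged, 113 to 167 for LPS, 100 to 190 for LPS against A23187, and 0 to 0 for LTB-4 and the A23187 interaction. Under A23187 genotype gave 1 to 2 (2 without positive replicate 1), and A23187 itself 0 to 3 (2 without negative and 3 without positive replicate 1). The LPS interaction gave 0 to 1 (1 without negative LPS replicate 3). Genotype at 0 h gave 2 to 105: 4 and 26 without negative replicates 1 and 2, 2 and 105 without positive replicates 1 and 2. PMA gave 11 to 183: 34 without the negative and 11 without the positive PMA sample. For 4 h against 0 h the range was 144 to 1224: 264 without negative 0 h replicate 1, 144 and 1224 without positive 0 h replicates 1 and 2, 1125 and 443 without negative 4 h replicates 3 and 5. Spleen gave 83 to 1024: 83 and 92 without the negative and positive spleen, 447 and 1024 without positive 0 h replicates 1 and 2. A lone sample left in a group is assumed to vary like the other groups. List tests with a random block were not run, since camera takes none.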

Other observations

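The test of genes beside the S100a9 locus and the comparisons by date code were chosen only after the data had been seen.

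The spleens of each genotype, 1 sample each, showed a similar profile of cell markers against granulocytes at 0 h, where the median over all probe sets was -0.36. The median log2 difference was 2.65 in the negative and 2.68 in the positive spleen for MHC class II genes, 1.98 and 1.66 for T and natural killer markers, 1.01 and 1.00 for B lymphoid markers and 0.31 and 0.77 for monocyte, macrophage and dendritic markers. It was -3.34 and -3.71 for specific and gelatinase granule proteins, -1.92 and -1.77 for azurophil granule proteins and -0.94 and -1.55 for erythroid markers. The spleens of each genotype were not tested against each other.

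Ctss lies on chromosome 3, as S100a9 does, 183 genes away. A hypothesis was that DNA inherited with the S100a9 locus might change its neighbours. Over the 40 measured genes within 100 genes on either side, the mean absolute moderated t of the averaged genotype difference was 0.730, and 64.3% of 10000 random gene sets of the same size were as high. The neighbours as a set did not stand out, but Ctss lies outside this range and a change in a few linked genes would not show in a mean, so the hypothesis stays open.

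Signals of 3 transcripts were compared by date code. Actb was 524.7 in the negative and 2413 in the positive spleen, 1170 to 3792 in the A23187 samples of the same date code (replicate 4) and 5766 to 135720 in the other 30 granulocyte samples. Against those 2 A23187 samples, 643 of the 681 probe sets called for spleen kept their sign, 318 of 325 up and 325 of 356 down, with differences at a median of 0.556 of those against 0 h. The same 2 spleens enter both differences and the calls, so some agreement in sign is built in. The second S100a8 probe set, on sub-array B, was 2308 to 3076 in these A23187 samples, 13444 and 7850 in the negative and positive spleen, and 25658 to 225239 in the other 30. Tmem59 was 209.8 to 28928 (median 3857) in the 16 samples of early and 35.0 to 2281 (median 131) in the 18 samples of late date codes, with overlap.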
